A study of Rattus norvegicus with 6 samples.

How the data were processed

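Renal cortex RNA of 6 male rats, 5 weeks old at purchase, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, with 3 animals per group as biological replicates, per the labels. Groups and replicate numbers were taken from the sample labels. The deposited scanner tables hold intensity values on a linear scale from Agilent Feature Extraction 10.7, per the submitters' processing notes; the processed signal in them is background-subtracted and not scaled between arrays, per the file headers. The other columns used, 0 or 1 flags for spots well above background, outlying or saturated, were also set by that software, per the file headers. A deposited value table of intensity values was compared with the scanner signals. Each column equalled the processed signal divided by a factor that brought its 75th percentile to 1, within an SD of at most 0.0059 log2, so it is linear and not centred per gene. Its column medians were 0.1102, 0.111 and 0.111 for vehicle and 0.1148, 0.1118 and 0.1125 for benzyl acetate.

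Values were log2 of the processed signal minus the array's 75th percentile over 61537 non-control probes, with spots flagged as outliers left out; no spot was saturated. The normalization is relative, so a change shared by most transcripts would not be seen. A probe entered when it was well above background on all 3 arrays of at least 1 group, which 42355 probes were. Probes were named by matching their accession, without version, to a RefSeq table of the GRCr8 assembly. Of all probes 28206 matched, giving 15645 symbols, and 33331 kept their accession or probe name. The array grid names an older rat build, so no coordinates are given. For each gene the probe of highest mean signal was used, leaving 31179 genes, of which 12276 had a symbol. Of the 118 genes named, 75 had several detected probes and for 23 these differed in sign. Probes of near-identical gene family members can share signal.

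Limma 3.58.1 in R 4.3.3 was fitted to both groups (lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes, threshold 0.05). Gene lists (46 lists, 874 genes, of which 747 were tested) were fixed before the data were examined and tested by camera with a preset correlation of 0.01, over lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Counts per list were also made with p-values adjusted over the list alone. These were not adjusted over the 46 lists, so a pass in some lists can arise by chance. Genes were named by a rule set in advance: the 10 of largest change in each direction past the threshold with separate groups and detection on all 6 arrays, filled with the lowest unadjusted p where too few passed, with the other conditions kept (here all 20 places); up to 3 genes per direction past the threshold and below background in a group (here none); up to 4 members of each list past the threshold or, where none passed, its 2 brightest members; and 20 genes in any case. Results of 3 genes the rule names are not reported here. Values of these genes are log2 differences, benzyl acetate minus vehicle, with n = 3 per group. Members that passed when adjusted over their list alone (except Atp6v1g3, which the rule names), and Cd3g, Gzma, Fabp4, Cd2, Cxcl2, Odam and Mfsd10, were named after their values were seen.

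Alternatives were the replicate number or the slide as a block, normexp with an offset of 50, quantile, median and cyclic loess normalization, other filters on dim probes, other rules for several probes, flagged spots kept, a trended robust prior, array weights, the deposited value table and leaving out each replicate. Normexp was run on the median spot signal in place of the mean. Restricting the test to probes matched to a symbol was chosen after seeing the data. Vehicle replicate 1 was on slide 1 and the other 5 arrays on slide 2. The slide as a block therefore takes vehicle replicate 1 out of the comparison. It is not independent of the fit that leaves that array out, and an effect of the slide cannot be told apart from that animal. No 2 arrays held identical signals. The fit was tested on simulated data with the measured means and SDs of 31165 genes and 200 changed genes in each of 10 data sets, where it recovered 29.1% of genes changed 1.5-fold, 62.5% of those changed 2-fold and 87.7% of those changed 4-fold, with 4.02% of calls false. These shares hold for 200 changed genes. With fewer changed genes, which was not simulated, the adjustment asks for a lower p, so fewer would be recovered. In the measured data Cryz, with a 2.52-fold difference, did not pass in limma (adjusted p = 0.271). Camera recovered 98% of lists shifted by 0.5 log2 and called 1.47% of unshifted lists, with genes simulated as independent. In the lists called in the measured data the estimated correlation ran from -0.019 (complement and acute phase) to 0.63 (T and NK cell markers). Apart from T and NK cell markers, their median log2 differences were only -0.081 to -0.21. Neither simulated share therefore describes these lists.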

Results

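Renal cortex from 6 male Sprague-Dawley rats was profiled on 1-colour Agilent expression arrays, 1 array per animal. For 4 weeks 3 rats were given corn oil (vehicle) and 3 were given benzyl acetate at 1000 mg/kg/day. Benzyl acetate is a fragrance and flavour ester that is hydrolysed to benzyl alcohol, oxidised to benzoic acid and excreted largely as the glycine conjugate hippuric acid. Between 69.0% and 72.0% of the 61537 probes were well above background on each array. The share was 69.4% ± 0.38 (SD, n = 3) with benzyl acetate and 71.2% ± 0.72 (SD, n = 3) with vehicle, an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The 75th percentile of the signal, by which each array was scaled, was 954 ± 61.2 (SD, n = 3) with benzyl acetate and 1036 ± 29.1 (SD, n = 3) with vehicle, and each treated array lay below each vehicle array (exact two-sided permutation p = 0.1). Pairs of arrays correlated at 0.990 to 0.994 across genes, within and between groups. Benzyl acetate replicate 3 stood apart, with the lowest 75th percentile, 883. Its 3' minus 5' difference of the Gapdh control probes was 2.62 log2, against 2.37 to 2.44 on the other arrays. On the first principal component, with 26.2% of the variance, it stood at 50.1, against -24.4 to -0.23 for the others. The number of arrays limits the precision.

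The comparison of benzyl acetate with vehicle asks which transcripts of the renal cortex differ after 4 weeks of dosing. No gene passed the threshold. Limma called 0 of 31179 genes higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.271. At an unadjusted p under 0.05 there were 1190 genes higher and 910 lower, 6.74% of those tested. The balance depended on the scaling, with 828 higher and 1276 lower under median scaling. The 3 treated arrays lay on one side of the 3 vehicle arrays for 12.8% of genes, where chance gives 10%. The typical 95% interval of a gene reached 0.27 log2 to either side, a 1.21-fold difference. Of the 12276 tested genes with a symbol, 11319 (92.2%) had an interval inside a 2-fold difference and 9462 (77.1%) inside a 1.5-fold difference. Without benzyl acetate replicate 1, limma called 2 genes lower, and without benzyl acetate replicate 3 it called 3 higher and 1 lower. Those 3 were not well above background on any vehicle array.

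The gene of lowest p with a symbol was Cryz, which encodes the quinone reductase zeta-crystallin. Its log2 signal relative to the array's 75th percentile was 2.60 ± 0.053 (SD, n = 3) with benzyl acetate and 3.94 ± 0.18 (SD, n = 3) with vehicle. The difference was -1.33 (95% interval -1.59 to -1.07), a 2.52-fold difference that did not pass the threshold in limma (adjusted p = 0.271). Over the alternatives this adjusted p ran from 0.0188 with normexp background correction to 0.672 with the replicate block. Guca2b, which encodes the natriuretic peptide uroguanylin, differed by -1.04 (-1.29 to -0.79). Tfrc, the transferrin receptor, differed by -0.81 (-1.07 to -0.55) and Slc17a5, the lysosomal sialic acid transporter, by -0.75 (SE 0.10). A dimmer probe of Slc17a5 gave 0.19, in the other direction. The others of the 10 genes of lowest p on the lower side, with log2 differences, were Plcg2 (-0.73), Kcns3 (-0.66), Zfp583 (-0.42), Dnmt3l (-1.41), Tsx (-1.34) and Capn13 (-0.63). Adjusted p-values of these 10 genes in limma were 0.271 to 0.591.

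On the higher side 9 genes of lowest p are given, with adjusted p-values in limma of 0.535 to 0.620, so none passed. Dkkl1 (0.95) and Plpp4 (0.83) had the highest log2 differences. Krt5 (0.37), a basal keratin, had an interval of 0.20 to 0.55. The others were Mospd4 (0.66), Cldnd2 (0.61), Calr3 (0.59), Thy1 (0.57), Mcmdc2 (0.55) and Apba1 (0.45). All 9 were dim, with vehicle means of the log2 signal from -5.92 (Mospd4) to -1.62 (Calr3), against 3.94 for Cryz. Krt5 stood at -4.90. On the lower side Zfp583 (-4.02), Capn13 (-2.97), Dnmt3l (-2.75) and Kcns3 (-1.88) had vehicle means in the same range, and the rest were brighter. An interval covers the spread between arrays only, and an effect of low signal on these differences was not tested. No gene past the threshold was below background in either group, so no fold bounds were formed.

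**Figure D1:**
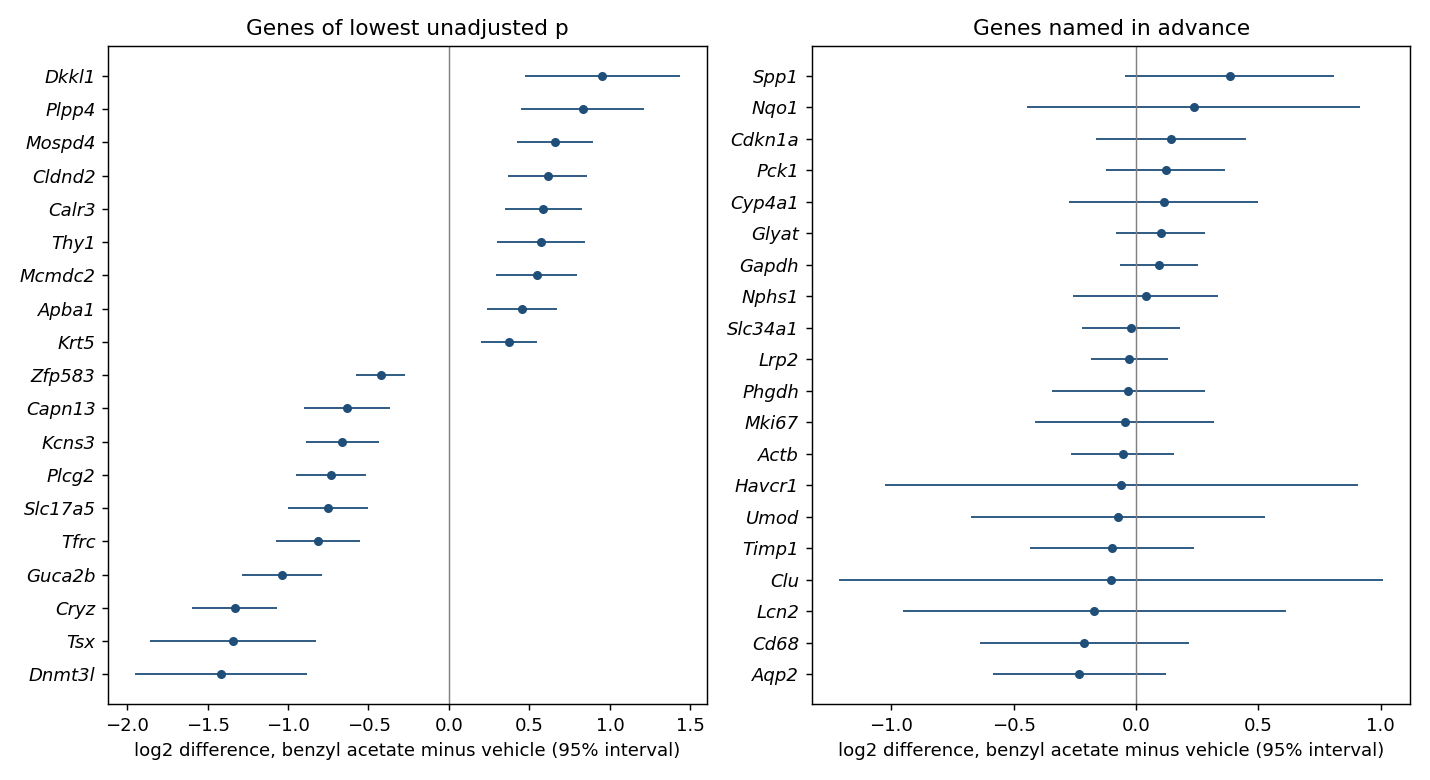
Log2 difference (x axis, benzyl acetate minus vehicle, 3 arrays per group) with its 95% interval for 19 genes of lowest unadjusted p (left) and the 20 genes named in advance (right). Cryz lies at -1.33 and Dkkl1 at 0.95; none of the 39 passed an adjusted p under 0.05.

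No marker of kidney damage passed over all genes. The injury marker Havcr1, which encodes KIM-1, differed by -0.06 with a wide interval of -1.03 to 0.91. Lcn2 differed by -0.17 (-0.95 to 0.61), Clu by -0.10 (-1.21 to 1.01), Spp1 by 0.38 (-0.045 to 0.81) and Timp1 by -0.10 (-0.43 to 0.24). The tubular injury and regeneration list had 25 tested members with a median log2 difference of -0.087, and its bright member Tff3 stood at -1.16 (-3.51 to 1.20). By camera the list did not pass (adjusted p = 0.11), but it was called lower with the replicate block (0.0434), the slide as a block (0.0344), normexp (0.0304), no filter on dim probes (0.0227) and without vehicle replicate 1 (0.0453). Its median was -0.012 (adjusted p = 0.422) without vehicle replicate 2, -0.001 (adjusted p = 0.104) without benzyl acetate replicate 2 and -0.027 (adjusted p = 0.293) from the lowest-signal probe. For cell cycle and proliferation the median was -0.059 over 28 members, with Ccnd1 (0.16), Kif11 (-0.18) and Mki67 (-0.047). Without benzyl acetate replicate 1 that median was -0.16 (adjusted p = 5.3e-05), and without benzyl acetate replicate 2 it was 0.085 (adjusted p = 0.344). With no filter on dim probes the adjusted p of the list was 0.0279. The p53 targets had a median of 0.048, with Perp (0.027) and Cdkn1a (0.14), and the apoptosis regulators one of -0.03, with Bcl2l1 (0.006) and Bax (0.048).

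None of the segment markers of the nephron passed over all genes. In the proximal tubule list the median of 31 members was 0.029, with Miox (0.10) and Fbp1 (0.056). Slc34a1, the sodium-phosphate cotransporter, differed by -0.022 (-0.22 to 0.18) and Lrp2, the endocytic receptor megalin, by -0.027 (-0.19 to 0.13). Thick ascending limb markers had a median of -0.14, with Umod (-0.073) and Egf (-0.14); the list passed without vehicle replicate 3 (adjusted p = 0.0072) and with normexp (0.0304), but not otherwise. Its median was -0.061 (adjusted p = 0.574) with the slide as a block and -0.061 without vehicle replicate 1. Distal convoluted and connecting tubule markers had a median of -0.091, lower in 8 of 8, with Klk1 (-0.035) and Wnk1 (-0.021); the adjusted p with the preset correlation was 0.0517. The list passed with normexp (0.0184), quantile normalization (0.0499), cyclic loess (0.0483), detection on all 6 arrays (0.0367) and array weights (0.0306), while without benzyl acetate replicate 1 the adjusted p was 0.2. Collecting duct and medulla markers had a median of -0.0047, with Aqp2 (-0.23). Adjusted over the list alone, 2 of its members passed: Slc26a4, the chloride-bicarbonate exchanger pendrin, at -0.96 (-1.41 to -0.51), and Atp6v1g3, a proton pump subunit of intercalated cells, at -0.63 (-0.96 to -0.31). Podocyte and glomerular markers had a median of -0.012, with Actn4 (0.13), Podxl (-0.049) and Nphs1 (0.04), and 1 member passed when adjusted over the list alone. The list of angiotensin system and calcium-phosphate genes had a median of -0.025, with Pth1r (-0.0061). Ammoniagenesis and acid handling had a median of 0.085, with Pck1 (0.12) and Glud1 (0.28), and 1 member, Slc26a4, passed when adjusted over the list alone.

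None of the genes of the route that handles benzoic acid passed over all genes. The glycine conjugation and acyl-CoA synthetase list had a median of 0.02 over 9 members. Glyat, the mitochondrial glycine N-acyltransferase, differed by 0.10 (-0.081 to 0.28) and Acsm2 by 0.038 (-0.21 to 0.29). Adjusted over the list alone, 1 member passed, Glyatl1 at -0.74 (-1.08 to -0.39). Glycine and serine metabolism had a median of 0.027, with Agxt2 (-0.17) and Phgdh (-0.032), and coenzyme A turnover one of 0.021, with Ppcs (-0.12) and Vnn1 (0.12). Aldehyde and alcohol oxidation had a median of 0.063, with Aldh7a1 (0.12) and Aldh1a1 (-0.018). Organic anion transport, which includes the hippurate carriers, had a median of 0.016, with Slc13a3 (0.026) and Slc22a6 (0.19). Conjugating enzymes had a median of 0.19, higher in 10 of 12, with Sult1c2 (0.21) and Nat8 (0.12); the list did not pass (adjusted p = 0.11), but passed without vehicle replicate 2 (adjusted p = 0.0112) and with the replicate block (0.0165). Without vehicle replicate 3 its median was 0.088 (adjusted p = 0.539). The cytochrome P450 list had a median of 0.10 and a mean of -0.43, with Cyp4a2 (0.091) and Cyp2c23 (0.13). Adjusted over the list alone, 1 P450 passed, Cyp2d4 at 0.45 (0.21 to 0.68).

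Metabolic and stress programmes did not pass either, apart from the lists described below. PPARalpha targets and fatty acid oxidation had a median of -0.0084 over 32 members, with Cyp4a1 (0.11) and Hadh (0.053); without vehicle replicate 3 the median was 0.10 (adjusted p = 0.0423) and without vehicle replicate 2 it was -0.071 (adjusted p = 0.122). Fatty acid synthesis had a median of 0.054, with Me1 (-0.12) and Acly (0.026), cholesterol biosynthesis 0.026, with Msmo1 (0.026) and Fdft1 (-0.0024), and gluconeogenesis and glycolysis 0.039, with Fbp1. All 29 tested oxidative phosphorylation genes had intervals inside 1.5-fold, with a median of 0.0062, Atp5f1a (0.062) and Cox4i1 (0.089). Cytosolic ribosomal proteins had a median of 0.022, with Rplp1 (0.048) and Rplp0 (0.091). NRF2 antioxidant targets had a median of 0.033, with Nqo1 (0.24), Ftl1 (0.06) and Fth1 (0.0007), and metallothioneins and zinc transport 0.049, with Mt1 (0.049) and Mt2A (0.075). The integrated stress response list had a median of -0.057, with Psat1 (-0.013), and passed with no filter on dim probes (adjusted p = 0.0401), while without benzyl acetate replicate 3 its median was -0.031 (adjusted p = 0.362). Heat shock proteins had a median of -0.0056, with Hspa8 (-0.27) and Hspe1 (0.017), and hypoxia targets -0.00033, with Pgk1 (0.0018) and Ndrg1 (0.35). Polyamine and arginine-creatine metabolism had a median of -0.018, with Ddah1 (0.10) and Oaz1 (-0.081). Immediate early genes had a median of -0.17, with Jund (0.0034) and Jun (-0.17); the list passed without vehicle replicate 3 (adjusted p = 0.0423), with normexp (0.0463) and with no filter on dim probes (0.0279), while without vehicle replicate 2 its median was -0.021 (adjusted p = 0.815). Circadian clock genes had a median of 0.13, with Dbp (0.24) and Tef (0.042). Apoptosis regulators had 1 member past the threshold when adjusted over the list alone, Bik (-0.43), and the list passed by camera with no filter on dim probes (adjusted p = 0.0401). The median of that list was 0.0045 (adjusted p = 0.381) without vehicle replicate 2 and -0.0033 without benzyl acetate replicate 2, and it was 0.0073 from the mean of a gene's probes and 0.011 from the lowest-signal probe; the direction of camera was lower in each of these fits. In the other 40 of the 46 lists no member passed when adjusted over the list alone. The 6 genes that did so had adjusted p-values in limma of 0.591 to 0.620 over all genes. The reference genes Actb (-0.055) and Gapdh (0.094) did not pass.

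Of the 46 lists, 7 fell by camera with a preset correlation of 0.01 and 0 rose. T and NK cell markers fell, with all 17 tested members lower and a median log2 difference of -0.56 (adjusted p = 7.7e-07, and adjusted p = 0.675 with an estimated correlation). Examples were the T cell receptor complex chains Cd3d, at -0.48, and Cd3g, at -1.07, and the cytotoxic granule genes Nkg7, at -0.31, and Gzma, at -0.50, none of which passed singly. The mean of the list over its members, relative to the 6 arrays, was 1.07 in vehicle replicate 3, 0.039 and -0.14 in the other vehicle arrays, and -0.30, -0.49 and -0.19 in the treated arrays. Without vehicle replicate 3 the median was -0.28 (adjusted p = 0.00098). Inflammatory cytokines and NF-kB targets fell, with 20 of 23 members lower and a median of -0.21 (adjusted p = 0.00061, and adjusted p = 0.675 with an estimated correlation). Its brightest members were Cx3cl1 (-0.092) and Il34 (0.074). Without vehicle replicate 3 its median was -0.13 (adjusted p = 0.0287) and with normexp -0.10 (adjusted p = 9.6e-05).

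Extracellular matrix and fibrosis genes fell, with 20 of 22 lower and a median of -0.18 (adjusted p = 0.0029, and adjusted p = 0.675 with an estimated correlation); Sparc (-0.059) and Bgn (-0.13) were the brightest. The call ended in 3 fits that left out 1 replicate, with medians of -0.072 without vehicle replicate 2 (adjusted p = 0.0821), -0.11 without benzyl acetate replicate 2 (adjusted p = 0.0823) and -0.14 without benzyl acetate replicate 3 (adjusted p = 0.0663). Interferon-stimulated genes fell, with a median of -0.21 over 23 members (adjusted p = 0.0045, and adjusted p = 0.688 with an estimated correlation), among them Mx2 (-0.00062) and Ifi27 (0.19). Benzyl acetate replicate 2 had the lowest mean of that list, -0.42, and without it the median was -0.068 (adjusted p = 0.301). The median was -0.15 without vehicle replicate 1 (adjusted p = 0.155) and -0.15 with the slide as a block (adjusted p = 0.126). The unfolded protein response list fell, with a median of -0.081 over 17 members (adjusted p = 0.0234, and adjusted p = 0.675 with an estimated correlation), with Hspa5 (-0.27) and Pdia6 (-0.11). Its call ended in 4 fits that left out 1 replicate, with medians of -0.043 without benzyl acetate replicate 1 (adjusted p = 0.443), -0.084 without benzyl acetate replicate 3 (adjusted p = 0.0535), -0.10 without vehicle replicate 1 (adjusted p = 0.0614) and -0.046 without vehicle replicate 3 (adjusted p = 0.22). Macrophage and monocyte markers fell, with a median of -0.13 (adjusted p = 0.0338, and adjusted p = 0.696 with an estimated correlation), with Lyz2 (-0.048), Tyrobp (-0.13) and Cd68 (-0.21); the median was -0.061 without vehicle replicate 3 (adjusted p = 0.43) and -0.0054 without benzyl acetate replicate 2 (adjusted p = 0.555). The macrophage call also ended under median scaling, at -0.16 (adjusted p = 0.0596), and among probes matched to a symbol, at -0.13 (adjusted p = 0.0682). Complement and acute phase genes fell, with a median of -0.11 (adjusted p = 0.0338, and adjusted p = 0.675 with an estimated correlation), with C4a (-0.14) and Serping1 (0.24). Its median was -0.16 without vehicle replicate 2 (adjusted p = 0.122), -0.075 without vehicle replicate 3 (adjusted p = 0.212), -0.11 without benzyl acetate replicate 2 (adjusted p = 0.0771) and -0.13 without benzyl acetate replicate 3 (adjusted p = 0.0535). The complement call also ended under median scaling, at -0.13 (adjusted p = 0.0652), under cyclic loess, at -0.11 (adjusted p = 0.0562), and among probes matched to a symbol, at -0.11 (adjusted p = 0.0697). From the mean of a gene's probes it was -0.15 (adjusted p = 0.0561) and from the lowest-signal probe -0.17 (adjusted p = 0.0566). With the calls kept, medians also moved by over 1.5 times in other fits. With normexp the median was -0.37 for T and NK cell markers and -0.12 for interferon-stimulated genes, and with the slide as a block it was -0.21 for complement, as without vehicle replicate 1. Without vehicle replicate 2 the median of T and NK cell markers was -0.89. Interferon-stimulated genes stood at -0.32 without vehicle replicate 3 and at -0.35 without benzyl acetate replicate 3, matrix genes at -0.29 without benzyl acetate replicate 1, the unfolded protein response at -0.14 without benzyl acetate replicate 2 and macrophage markers at -0.24 without benzyl acetate replicate 3. The count of 7 lists became 3 without benzyl acetate replicate 2 and 4 without benzyl acetate replicate 3. By fry, 0 of the 46 lists passed in either form of its test, with 1 list at an unadjusted p under 0.05 for one direction and 9 for either direction. Camera with an estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05.

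**Figure D2:**
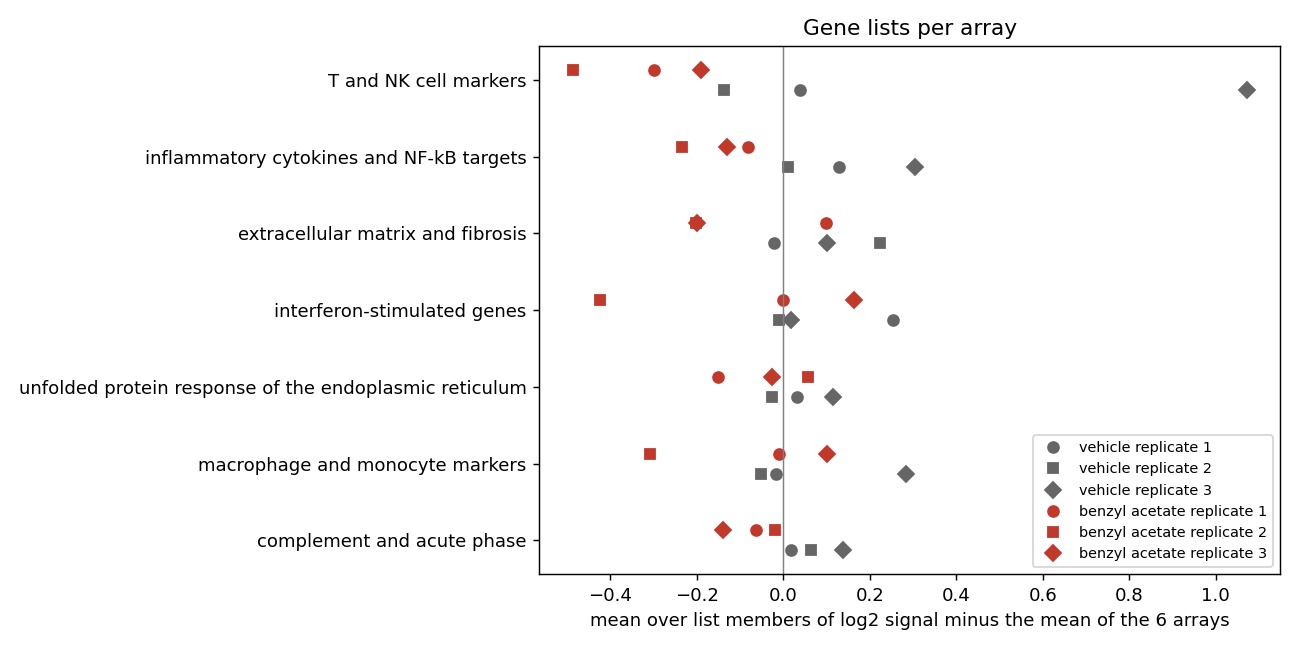
Mean over list members of the log2 signal minus the mean of the 6 arrays (x axis) for the 7 lists that fell by camera, 1 symbol per array. Vehicle replicate 3 stands at 1.07 for T and NK cell markers, and benzyl acetate replicate 2 at -0.42 for interferon-stimulated genes.

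Markers of other cell types and tissues did not pass. B and plasma cell markers had a median of -0.43 over 6 members, with Cd74 (-0.35) and RT1-Da (-0.42). That list passed with the replicate block (adjusted p = 0.0165), and without benzyl acetate replicate 2 its median was -0.15. Neutrophil and mast cell markers had a median of -0.12, with Tpsab1 (0.068) and S100a9 (-0.40). Endothelial markers had a median of 0.075, with Plvap (0.076) and Kdr (0.25), and vascular smooth muscle and pericyte markers 0.15, with Notch3 (-0.094). Red blood cell markers had a median of -0.0052, with Hba-a1 (0.04) and Hbb (0.039), and adrenal cortex markers 0.074, with Mrap (-0.32) and Hsd3b1 (0.074). Adipocyte markers had a median of -0.093, with Adipoq (0.34) and Cidea (-0.093); the list passed without vehicle replicate 3 (adjusted p = 0.0287) and with no filter on dim probes (0.038), while without vehicle replicate 2 the median was 0.0097 (adjusted p = 0.248), with the direction of camera still lower. Their mean per array was 0.23, 0.54 and -0.16 with vehicle and -0.31, -0.11 and -0.20 with benzyl acetate. Fabp4, whose values enter these means, was not well above background on any benzyl acetate array, and neither were Cd2 of the T and NK cell list and Cxcl2 of the inflammatory list. The 39 lists that did not pass had adjusted p-values of 0.0517 to 0.905 by camera with the preset correlation.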

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

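The count of 0 genes past the threshold held in both directions in 18 of 21 alternatives. Among these, the slide as a block and leaving out vehicle replicate 1 compare the same arrays. Limma called 2 genes lower with normexp background correction, Cryz and 1 unnamed transcript. Leaving out 1 replicate gave 0 to 3 genes higher and 0 to 2 lower, with fewer samples in the fit. Without benzyl acetate replicate 1 the 2 calls were Mfsd10 and another unnamed transcript. Without benzyl acetate replicate 3 the 4 calls were Odam, 2 unnamed probes and the same unnamed transcript as with normexp. The log2 signals of that transcript were -3.35, -3.28 and -3.79 with benzyl acetate and -1.43, -1.49 and -1.60 with vehicle. It was well above background on all arrays, and it did not pass with the main processing. Odam and the 2 unnamed probes were not well above background on any vehicle array and were not in the main test. Their log2 signals in vehicle replicates 1, 2 and 3 were -8.14, -8.23 and -8.35, the same for each. Their differences are therefore only lower bounds, and the spread of these vehicle values does not measure that of the transcripts. At an unadjusted p under 0.05 there were 5497 genes higher and 1081 lower with no filter on dim probes, and 371 and 367 among probes matched to a symbol, an alternative chosen after seeing the data that tests fewer genes. The higher share of genes at an unadjusted p under 0.05 was 56.7% and became 67.8% with normexp and 39.4% under median scaling. It was 49.3% under quantile normalization, 49.0% under cyclic loess and 83.6% with no filter on dim probes. The share thus followed the scaling and the filter, so it gives no direction of a treatment effect. The cause was not tested. No alternative moved the median of all genes from 0 by more than 0.039 log2. Dim probes limit what can be read: 69.0% to 72.0% of probes per array were well above background.

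With the replicate block limma called 0 genes in either direction, and camera 1 list higher and 9 lower. Same-numbered arrays did not deviate together, with correlations of deviations of -0.11, 0.0075 and 0.00095, so the numbers were not taken to pair the animals. The 7 lists that fell became 11 with normexp, 13 with no filter, 0 with an estimated correlation and 0 by fry; none rose in those 4. Leaving out 1 replicate gave 3 to 7 lists lower and 0 to 1 higher; the cause was not tested.

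Among 2478 recomputed values of the 118 named genes, 1 passed the threshold (Cryz with normexp) and 169 changed sign, 26 of these by more than 1 SE. The cause was not tested. From the lowest-signal probe, log2 differences of the other sign were Slc17a5 0.1858, Hsd3b1 -0.3196, Aldh1a1 0.0013, Fdft1 0.0452, Aqp2 0.0743, Rplp1 -0.0024, Bgn 0.3299, Acly -0.109, Fbp1 -0.0436, Pgk1 -0.1071, Psat1 0.0844, Fth1 -0.0169, Atp5f1a -0.0746, Actn4 -0.0059, Ddah1 -0.0034, Hadh -0.0401, Miox -0.1239, Notch3 0.0325, Nqo1 -0.0052. From the mean of a gene's probes, log2 differences of the other sign were Hsd3b1 -0.1226, Fdft1 0.0214, Wnk1 0.0205, Bgn 0.0989, Acly -0.0413, Pgk1 -0.0527, Psat1 0.0358, Fth1 -0.0168, Atp5f1a -0.0065, Miox -0.0144. With the slide as a block, log2 differences of the other sign were Aldh1a1 0.0262, Bcl2l1 -0.0545, Msmo1 -0.0142, Acsm2 -0.0276, Hspe1 -0.0525, Pgk1 -0.0497, Mx2 0.0317, Fth1 -0.0124, Perp -0.0024, Cyp4a2 -0.0133, Hadh -0.0946, Pth1r 0.0572, Umod 0.1043, Notch3 0.0179, Nqo1 -0.054. With normexp background correction, log2 differences of the other sign were Bcl2l1 -0.0267, Wnk1 0.025, Hspe1 -0.0279, Jund -0.0243, Mx2 0.0187, Fth1 -0.0532, Perp -0.0378, Hba-a1 -0.0216, Havcr1 0.0541, Slc34a1 0.0053. Under quantile normalization, log2 differences of the other sign were Bcl2l1 -0.0088, Fdft1 0.0047, Fbp1 -0.0236, Acsm2 -0.0054, Hspe1 -0.0061, Pgk1 -0.0272, Jund -0.0066, Mt1 -0.0199, Ftl1 -0.0383, Fth1 -0.0664, Slc13a3 -0.0298, Atp5f1a -0.0288, Miox 0, Hba-a1 -0.0353. Under median scaling, log2 differences of the other sign were Bcl2l1 -0.023, Msmo1 -0.0028, Acly -0.0027, Hspe1 -0.0125, Pgk1 -0.0273, Jund -0.0257, Fth1 -0.0284, Slc13a3 -0.0028, Perp -0.002. Under cyclic loess, log2 differences of the other sign were Bcl2l1 -0.0105, Hspe1 -0.0097, Pgk1 -0.0252, Jund -0.0084, Fth1 -0.0353, Slc13a3 -0.0096. With array weights, log2 differences of the other sign were Hspe1 -0.0036, Mx2 0.0118, Fth1 -4e-04, Pth1r 0.0172. Over the fits that leave out 1 replicate, genes that changed sign had ranges of Cidea -0.271 to 0.0163, Hsd3b1 -0.2106 to 0.2587, Aldh1a1 -0.045 to 0.0262, Bcl2l1 -0.0545 to 0.0827, Ccnd1 -0.0297 to 0.2868, Msmo1 -0.0238 to 0.0711, Fdft1 -0.0377 to 0.0449, Tef -0.0762 to 0.1217, Vnn1 -0.1406 to 0.39, Nat8 -0.0257 to 0.2452, Klk1 -0.1043 to 0.048, Wnk1 -0.0883 to 0.0628, Bgn -0.2634 to 0.0064, Me1 -0.3534 to 0.0435, Acly -0.0538 to 0.1198, Fbp1 -4e-04 to 0.0937, Phgdh -0.1386 to 0.0487, Acsm2 -0.0276 to 0.1088, Hspe1 -0.0525 to 0.0556, Pgk1 -0.0497 to 0.0374, Jund -0.0902 to 0.0629, Il34 -0.0494 to 0.1896, Psat1 -0.0772 to 0.0471, Mx2 -0.1037 to 0.0627, Ifi27 -0.035 to 0.4398, Lyz2 -0.1939 to 0.1173, Tyrobp -0.2867 to 0.0267, Mt1 -0.0462 to 0.138, Fth1 -0.014 to 0.0285, Perp -0.0055 to 0.089, Podxl -0.2026 to 0.0655, Cyp4a2 -0.0133 to 0.1788, Hadh -0.0946 to 0.161, Hba-a1 -0.0235 to 0.0939, Hbb -0.0309 to 0.0956, Pth1r -0.0713 to 0.0572, Umod -0.359 to 0.1043, Clu -0.5907 to 0.2975, Notch3 -0.2344 to 0.0179, Havcr1 -0.514 to 0.1767, Lcn2 -0.458 to 0.0683, Timp1 -0.1796 to 0.0279, Slc34a1 -0.0812 to 0.0406, Lrp2 -0.0454 to 0.0047, Nphs1 -0.0298 to 0.1448, Nqo1 -0.054 to 0.4881, Mki67 -0.1569 to 0.1106, Cyp4a1 -0.0566 to 0.2019, Actb -0.1199 to 0.0046.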

Other observations

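The tests of the T and NK cell markers and the count of splits for genes past the threshold were chosen after the result was seen, and so were the conditions on spread or coverage applied to the adipocyte markers, the other probes and the type B markers. Intercalated cells of the collecting duct, which secrete acid (type A) or bicarbonate (type B), were examined with marker lists added after the value of pendrin was seen. Slc4a1, Atp6v1b1, Atp6v0d2, Atp6v1c2, Atp6v1g3, Foxi1 and Rhbg are also members of the fixed acid handling or collecting duct lists, so their values are not additional evidence. Pendrin (Slc26a4), the apical exchanger of type B cells, had a log2 difference of -0.96 that did not pass over all genes. Other type B markers were Insrr (-0.60), Hmx2 (-0.58) and Slc4a9 (0.065). Type A markers were Slc4a1 (0.093), Aqp6 (0.17) and Dmrt2 (0.048). Markers listed for intercalated cells without a split by type were Atp6v1b1 (-0.069), Atp6v0d2 (-0.26), Atp6v1g3 (-0.63), Atp6v1c2 (-0.28), Foxi1 (-0.43) and Rhbg (0.016). None passed over all genes in limma.

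A hypothesis is that the treated cortex held fewer type B cells. The median of the other type B markers was -0.5755 in 3 genes, past a line of -0.5 chosen before their values were seen. That line was a choice, and pendrin itself stood lower, at -0.96. Against the hypothesis, the 95% interval of Slc4a9, -0.36 to 0.49, excludes a difference of -0.5. A change of regulation within the cells stays open and was not tested, and 3 markers that differ cannot decide between it and fewer cells.

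T and NK cell markers had a median log2 difference of -0.56, a call of camera with the preset correlation only (adjusted p = 7.7e-07, and adjusted p = 0.675 with an estimated correlation). The exact two-sided permutation p of the list mean per array was 0.1, the smallest possible, and 0.657 when adjusted over the lists. Without vehicle replicate 3 their median difference was -0.2828, between a value near 0, which 1 animal with more lymphoid transcripts would leave, and the full difference. In vehicle replicate 3 these markers exceeded the other vehicle arrays by a median of 1.01 log2 and B and plasma cell markers by 0.3154. Adipocyte markers differed by a median of -0.3509, with 3 of 9 genes higher. Their standard error of 0.42 was taken over the genes of this array and does not measure the spread between animals. With a single array, lymph node or perirenal fat in that sample is therefore neither excluded nor needed, and an effect of treatment on resident lymphocytes may also contribute.

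For the 10 genes of lowest p on the lower side, a variant under a probe in these outbred rats is a possible explanation. Of these genes 3 had other detected probes, 4 in all, with a median log2 difference of -0.6502. Both other probes of Tfrc (-0.84 and -0.46) and that of Guca2b (-0.92) went the same way, and that of Slc17a5 (0.19) did not. For Cryz and the others with 1 detected probe this cannot be told apart from a change in level.

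Splits of the 6 arrays into 3 and 3 are too few, at 10, for a share under 0.05. All 10 gave 0 genes past the threshold, the real split and the highest other alike. The real split gave 2100 genes at an unadjusted p under 0.05, which 1 of the 10 reached, the real split included, and the highest other gave 1881. For lists that shifted by camera with the preset correlation, 3 splits gave 7 or more, the real one gave 7 and the highest other 12.

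Odam, named after its values were seen, was well above background in benzyl acetate replicates 1 and 2 (log2 signals of -3.16 and -3.53) and in none of the other 4 arrays. Mfsd10 stood at -3.45 and -3.47 in benzyl acetate replicates 2 and 3, at -1.63 in benzyl acetate replicate 1 and at -1.50 to -1.55 with vehicle.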
